A study of Mus musculus with 2 samples.

How the data were processed

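Gene expression was measured with 1-colour Illumina bead arrays in cultured mouse embryonic fibroblasts of C57BL background. The first sample was a line without p53 (Trp53, a transcription factor that restrains growth after DNA damage), which served as the control. The other lacked both p53 and Dnmt1, the enzyme that copies DNA methylation onto newly made DNA. Per the labels' protocols, both lines grew in serum-containing medium, total RNA was taken with TRIzol, and it was amplified and labelled with biotin. Each genotype had 1 deposited sample, called an array here, so 2 arrays were compared. Groups were taken from the genotype in the labels.

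The deposited probe intensity values were on a linear scale and, per the file headers, not normalized. The scanner software and any earlier background step were not given in the sources used here. A detection p-value was deposited beside each intensity. All detection p-values on both arrays were multiples of 1 in 4 times 798, within a tolerance of 0.002 of a step of 1 in 798, and 50.8% of those of the control array and 49.0% of those of the Dnmt1-null array fell on whole steps of 1 in 798. Each deposited value therefore appeared to be a mean of 4 measurements against 798 negative controls. Whether these were 4 hybridisations or 4 parts of an array was not given in the sources used here, and their own spread was not used. A second deposited table held intensity values processed by the authors. Set against the unprocessed signals, its columns were linear, in nearly the same rank order (Spearman rho across probes 0.99998 for the control and 0.99997 for the Dnmt1-null array), lower by a background of about 136 and 116 units, and scaled to a shared mean of 507. The medians of its columns were 14.2 and 13.8, and 26.7% and 26.4% of its values lay below 0. The scale and the direction of these columns were thus settled by comparison, while the exact background and scaling method stayed unknown.

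Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by the normexp method with negative-control parameters inferred from the detection p-values, added an offset of 16, applied quantile normalization between the arrays and took log2. A probe was called detected at a detection p-value under 0.01. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. For 23962 probes the Entrez identifier matched a current symbol in a RefSeq gene table of the assembly GRCm38.p6, and 0 were renamed. This table also gave the chromosome and the order of genes, and no coordinates were used. For each of the 16593 genes, 4777 of them with more than 1 probe, the probe with the highest mean normalized level over both arrays was used. That choice ignores the sign of the difference but not its size. For a gene near background on 1 array it tends to take the probe brightest on the other, which favours a large difference. With the mean of all probes of a gene instead, 295 genes were higher and 236 lower by 2-fold or more in the Dnmt1-null line. Among 160 further detected probes of genes past the 2-fold rule, 158 differed in the same direction, 101 also by 2-fold or more, and 0 by 2-fold or more in the opposite direction. The median gap between probes of a gene was 0.13 log2.

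Differences are Dnmt1-null minus control on the log2 scale. With 1 array per group no test was possible, so no p-value is given for any difference, and the number of arrays limits the precision of every value. Genes were counted by a fixed rule of size: detected on at least 1 array and different by 2-fold (1 log2) or more. Where a gene was not detected on 1 array, its fold is a lower limit, written "at least". It was computed against the higher of the dim probe's own value and the lowest normalized value of a detected probe on that array, which was 5.57 log2 on the control and 5.66 log2 on the Dnmt1-null array. As a measure of scatter, a robust SD of the difference was taken over the 500 genes nearest in mean level, and it describes genes of these arrays, not replicates. For gene lists, the median measured difference of the detected members was set against 10000 random lists of the same size matched on mean level in 20 bins, and its percentile describes these arrays only. A percentile below 2.5 or above 97.5 was read as standing apart, and lists with fewer than 3 detected members had no median. Bootstrap intervals of list medians used 2000 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the plots.

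The rule for named genes took Dnmt1 and Trp53, the 20 largest increases and the 15 largest decreases, and from each list up to 4 members with the largest difference of 2-fold or more. Where fewer than 2 members of a list reached it, up to 2 detected members with the highest mean level were taken. A fixed set of germline genes was named whatever its values, namely Dazl, Tex19.1, Mael, Piwil2, Asz1, Mov10l1, Tdrkh, Sycp3, Hormad1, Slc25a31, Rpl10l, Taf7l, Stk31 and Ddx4. Genes outside this rule are marked where they are named. The groups, this rule, the 21 gene lists, the thresholds and most alternatives were set before the data were examined. The lists covered germline genome defence, meiosis, testis and oocyte genes, X-linked germline and cancer-testis genes, pluripotency, imprinted genes, the interferon response, p53 targets, DNA methylation and chromatin machinery, extracellular matrix, and epithelial, endothelial, haematopoietic, neural, muscle and trophoblast markers. The remaining lists were proliferation genes, Hox genes, sex chromosome genes, housekeeping genes and stress response genes.

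The steps were tested on simulated arrays made from the 16593 genes for the comparison of the Dnmt1-null line with the control, with noise of 0.2 log2 (SD) and 100 genes raised and 100 lowered by 4-fold. The rule called 100% of the raised and 94% of the lowered genes, and 3 of 9702 detected unchanged genes. All changed genes were drawn from those detected in the control, so rises from undetected signal were not tested. The noise was a fixed choice, while real differences of genes detected on both arrays had a robust SD of 0.34 log2. More genes were detected than the 7727 of the real arrays, so these rates may not carry over to them. Of 200 unchanged lists of 20 genes, 3% fell outside the middle 95%. The alternatives were no background correction, normexp with an offset of 50, neqc with an offset of 50, median scaling, cyclic loess, the authors' processed values with a floor of 16 units, a detection p-value under 0.05, no filter on dim genes, the mean of all probes of a gene, differences with or without lower limits, and thresholds of 1.5-fold, 3-fold and 4-fold. Re-centring on the genes detected on both arrays, and leaving out X-linked and Y-linked genes, were added after seeing the data. All columns with sample values were used. Probes without a gene symbol were left out of the gene counts and lists, since no gene could be named from them.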

Results

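The data compared the transcripts of mouse embryonic fibroblasts without p53 with those of fibroblasts without both p53 and Dnmt1, on 1 array per genotype. Fibroblasts that lose Dnmt1 fail to maintain DNA methylation, and loss of p53 lets such cells keep growing in culture. The title of the series names promoter methylation and genome defence in the germline, so the comparison asks which genes, germline genes among them, differ in somatic cells without the maintenance methyltransferase. The median signal of the 25697 probes was 150.5 units on the control and 129.8 units on the Dnmt1-null array. On the control array 10302 probes (40.1%) were detected, and on the Dnmt1-null array 10048 (39.1%). Each genotype had 1 deposited sample and no separate replicate values, so all folds below are differences between 2 samples.

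Dnmt1 itself was measured by 1 probe (ILMN_2720451) and was 4.54-fold lower on the Dnmt1-null array, at 10.63 log2 in the control and 8.44 log2 in the Dnmt1-null line. The difference of -2.18 log2 compared with a scatter of 0.36 log2 among genes of similar level. The transcript was still detected in the Dnmt1-null line, and the position of the probe relative to the disrupted part of the gene was not determined here. A probe outside that part would not check the label. Trp53 and Rpl10l had 0 probes under their names, so the loss of p53, shared by both lines, was not checked on the arrays.

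Of 16593 genes, 7727 were detected on at least 1 array, 6850 of them on both, 367 on the Dnmt1-null array alone and 510 on the control array alone. In the Dnmt1-null line 348 genes (4.50% of those detected) were higher by 2-fold or more and 287 (3.71%) were lower. Of the higher genes, 151 were not detected in the control, and of the lower genes, 109 were not detected in the Dnmt1-null line. At 8-fold or more, 44 genes were higher and 17 lower. Levels on the arrays correlated across genes with a Pearson r of 0.936 and a Spearman rho of 0.939, where genes are not independent replicates. Genes detected on both arrays had a median difference of -0.03 log2 and a robust SD of 0.34 log2. Without background correction the counts fell to 181 higher and 132 lower, and with the authors' processed values 449 genes were lower.

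**Figure D1:**
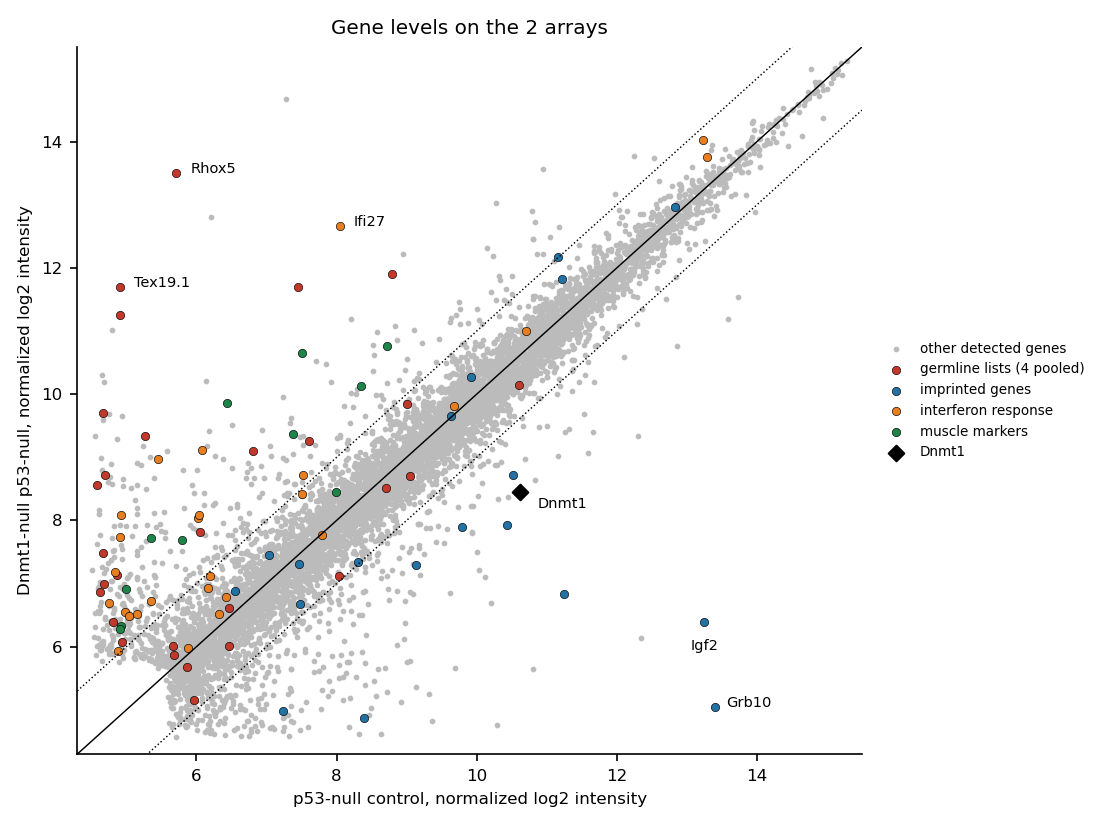
Normalized log2 intensity of each gene detected on at least 1 array, in the p53-null control (x axis) and the Dnmt1-null p53-null line (y axis). Points are genes, coloured by gene list, the solid line marks equal levels and the dotted lines 2-fold differences. Rhox5 and Tex19.1 lie far above the upper dotted line and Grb10 and Igf2 far below the lower one.

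The largest increases included genes of the germline and placenta. Rhox5, an X-linked homeobox gene of the reproductive tract, was at least 222-fold higher, rising from 5.71 log2 without detection to 13.51 log2. Tex19.1, a germ cell gene that restrains retrotransposons, was at least 70.6-fold higher, and Fmr1nb, a testis gene next to Fmr1, at least 51.8-fold. Psg23, of the pregnancy-specific glycoprotein family, was 168-fold higher, and Plac8, first described in placenta, 97.1-fold. Xlr4a was 19-fold higher, Magea2, of the melanoma antigen family, at least 17.6-fold, and Nlrp4c, of an NLR gene group active in oocytes, at least 17.1-fold. Asz1, a germ cell protein needed for piRNA production, was at least 13.6-fold higher. Rhox5, Xlr4a, Magea2, Psg23 and Nlrp4c belong to families of similar sequence, so their probes can also bind paralogs and their values are uncertain. With the mean of all its probes Nlrp4c differed by 0.35 log2, below 2-fold.

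Other large increases came from genes outside the germline lists. Slc47a1, an exporter of organic cations, was at least 43.9-fold higher, and Casp1, the protease of inflammasomes, at least 26.6-fold. Nckap1l, an actin regulator of blood cells, was at least 24.6-fold higher, Ifi27, an interferon-induced gene, 24.5-fold, and Amhr2, the receptor of anti-Müllerian hormone, at least 17.4-fold. Ctsk, a collagen-degrading protease, was 16.7-fold higher, the zinc finger gene Zfp985 at least 16.4-fold, and the glutathione transferase gene Gstp2 at least 13.8-fold. Pkd1l2, of the polycystin family, was at least 13.7-fold higher, 4930550L24Rik at least 13.2-fold, and Pla1a, a phospholipase, at least 12.2-fold.

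The 15 largest decreases included 3 imprinted genes. Grb10, an imprinted adaptor of growth factor receptors, fell from 13.40 log2 to 5.05 log2 without detection, at least 214-fold lower. Igf2, an imprinted fetal growth factor, was 115-fold lower, and Cdkn1c, an imprinted inhibitor of the cell cycle, 21.3-fold. The heparin-binding growth factor Mdk was 73.8-fold lower. The microfibril gene Mfap2 was at least 35.3-fold lower, the cartilage collagen gene Col2a1 at least 16.2-fold, and Mfap4 at least 9.57-fold. Eif2s3y, a Y-linked translation factor gene, was at least 24.9-fold lower. Cdo1, which oxidises cysteine, was at least 13-fold lower, the chromatin remodeller gene Smarca1 at least 12.7-fold, and the transcription factor gene Zic1 11.4-fold. Igdcc4 was at least 11.2-fold lower, the teneurin gene Tenm3 at least 9.68-fold, the cholesterol hydroxylase gene Ch25h at least 9.51-fold, and Dner, a Notch-related membrane protein gene, at least 8.38-fold. The 75 genes named by the rule that passed 2-fold differed by 1.02 log2 (Fas) or more, and their scatter among genes of similar level was 0.60 log2 (Dppa5a) or less.

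Detected germline genes, pooled over 4 lists, were higher in the Dnmt1-null line. The 4 germline lists pooled had 127 genes on the array, of which 29 were detected, 27 in the Dnmt1-null line and 15 in the control. Of these 29, 16 were higher by 2-fold or more and 0 lower. Some of the 16 are paralogs of similar sequence, whose probes may not be separate measurements. Their median difference was 1.76 log2, at percentile 100 of level-matched random lists, whose middle 95% ran from -0.24 to 0.17 log2. The remaining 98 (77.2%) were detected on neither array, and over all 127 genes without a filter on dim genes the median was 0.056 log2 at percentile 99.99. With bounded differences it was 1.42 log2 and without background correction 0.93 log2, both at percentile 100.

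In the list of germline genome defence genes, which act in the piRNA pathway and the silencing of transposons, 9 of 23 members on the array were detected, 4 were higher, 0 lower and 5 in between. Besides Tex19.1 and Asz1, the helicase gene Mov10l1 was at least 3.79-fold higher and Piwil2, a piRNA-binding protein gene, at least 2.96-fold. The list median was 1.13 log2, at percentile 99.99. Without a filter on dim genes it was 0.05 log2 over all 23 members, at percentile 89.9, because 14 members were detected on neither array. Dazl, an RNA-binding protein gene of germ cells, was detected in the Dnmt1-null line alone and was at least 1.42-fold higher, which is below the rule. Tdrkh, a tudor domain gene, differed by -0.92 log2. Mael, Stk31, Ddx4, Sycp3, Hormad1 and Slc25a31 were detected on neither array. Without background correction Mov10l1 and Piwil2 no longer passed 2-fold, nor did Piwil2 with normexp and an offset of 50.

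Of the meiosis genes, 8 of 34 on the array were detected, 3 were higher, 0 lower and 5 in between. Mnd1, which acts in meiotic recombination, was 8.61-fold higher, Stag3, the meiotic cohesin gene, 3.38-fold, and Tex11, an X-linked meiosis gene, at least 2.68-fold. The list median of 0.27 log2 lay at percentile 94.8, inside the limits of random lists, and at a detection p-value under 0.05 it lay just outside them, with 0.34 log2 at percentile 97.6. Without background correction the median was 0.093 log2, and Stag3 and Tex11 fell below 2-fold, Tex11 also with normexp or neqc and an offset of 50. Among testis and oocyte genes 4 of 36 were detected, and 2 were higher, the tubulin genes Tuba3a (4.89-fold) and Tuba3b (3.16-fold), whose sequences are near identical. The other 2 were detected in the control alone and lay within 2-fold, so the rise of this list rested on the 2 tubulin genes. The list median was 0.73 log2, at percentile 97.3, just inside the limits of random lists. It lay outside them under 5 of 11 alternatives, among them bounded differences (percentile 99.3), while at a detection p-value under 0.05 it was -0.19 log2.

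**Figure D2:**
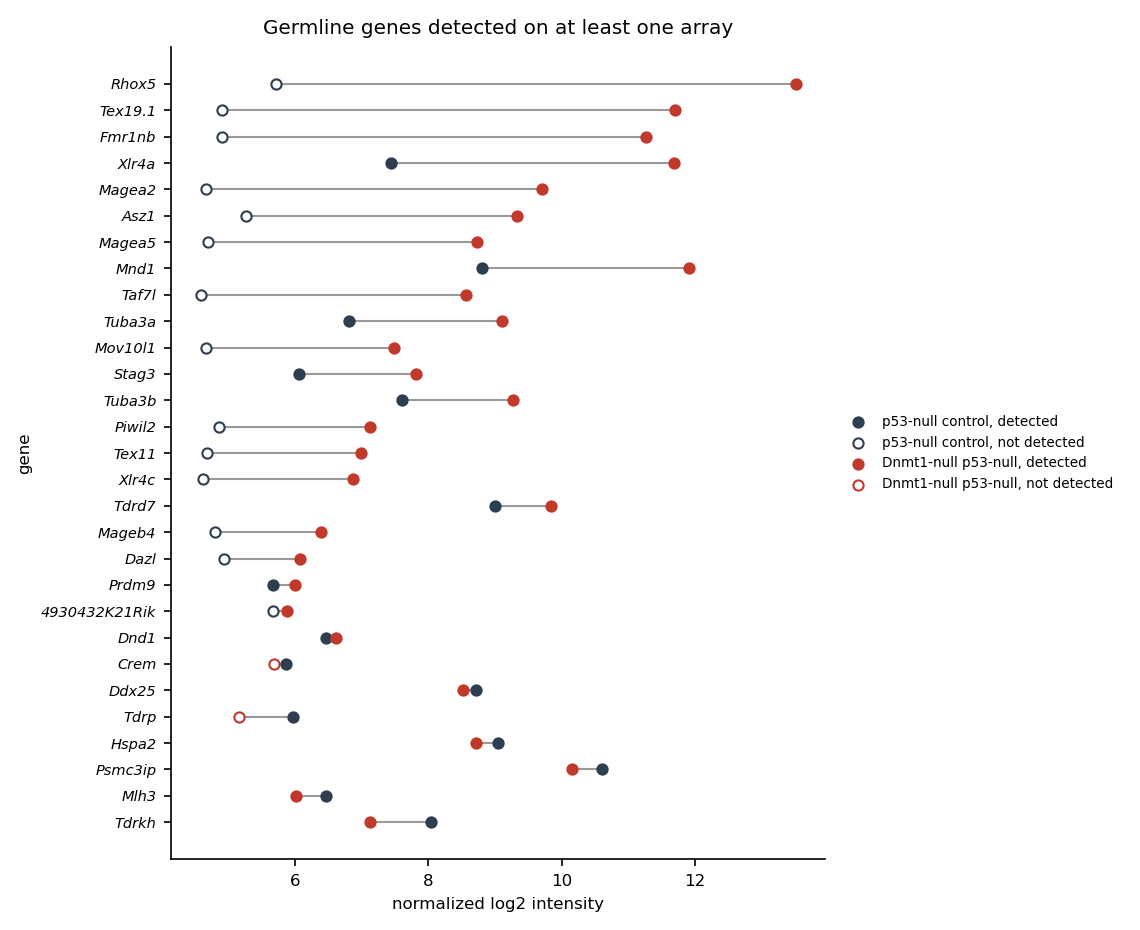
Normalized log2 intensity of the 29 germline genes detected on at least 1 array, in the p53-null control (dark) and the Dnmt1-null p53-null line (red). Filled circles are detected values and open circles values not detected, and grey lines join the values of a gene. Rhox5 has the widest gap, from 5.71 to 13.51 log2, and Tdrkh lies lower in the Dnmt1-null line, by -0.92 log2.

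X-linked germline and cancer-testis genes had a list median of 4.14 log2 at percentile 100, with 8 of 34 members detected, 7 higher and 0 lower. Of the 8, 1 was detected in the control, so most measured differences start from undetected signals. With bounded differences the median was 3.65 log2 and without background correction 2.53 log2, both at percentile 100, and over all 34 members without a filter on dim genes it was 0.12 log2, at percentile 99.99. Besides Rhox5, Fmr1nb, Xlr4a and Magea2, Taf7l, a germ cell relative of a general transcription factor subunit, was at least 8.02-fold higher. Magea5 (at least 8.94-fold) and Xlr4c (at least 2.47-fold), named after their values were seen, were the others. Magea5 and Magea2 are of the same family, as are Xlr4c and Xlr4a, so their probes may not be separate measurements. The X chromosome held 3.30% of the detected genes with a known chromosome, 5.76% of the higher genes (20 of 347), 6.27% of the lower genes (18 of 287) and 23.3% of the genes higher by 8-fold or more (10 of 43). Members of this list were among the X-linked genes higher by 8-fold or more, so that share is not separate from the list.

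Pluripotency and primordial germ cell genes went both ways. Of 27 on the array 8 were detected, 1 was higher (Dppa5a, a pluripotency-associated gene, at least 2.11-fold), 1 lower (Lefty1, a secreted inhibitor of Nodal, at least 3.22-fold) and 6 in between. The list median of 0.44 log2 lay at percentile 98.5, and this call was lost under 4 of 11 alternatives. These were a detection p-value under 0.05 (0.048 log2), no filter on dim genes (-0.019 log2), the mean of all probes (0.24 log2) and bounded differences (0.15 log2), and Dppa5a fell below 2-fold under 5 settings and Lefty1 without background correction.

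Imprinted genes were lower in the Dnmt1-null line. Of 38 on the array 19 were detected, and 9 were lower, 1 higher and 9 in between, with a list median of -0.97 log2 at percentile 0. Besides Grb10, Igf2 and Cdkn1c, the neuronal gene Nnat was at least 6.63-fold lower, and Dcn, the gene of the matrix proteoglycan decorin, was 3.58-fold lower. Named after their values were seen, Dlk1, a Notch-related growth regulator gene, was 5.70-fold lower, Igf2r, which clears Igf2, 3.71-fold, Mest 3.48-fold and Ppp1r9a at least 2.98-fold, while Ndn was 2.02-fold higher. Over all 38 members, without a filter on dim genes, the median was -0.031 log2 at percentile 27.8.

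Interferon response and antigen presentation genes were higher. Of 49 on the array 26 were detected, all 26 of them in the Dnmt1-null line and 14 in the control. Of these 26, 11 were higher, 0 lower and 15 in between, with a list median of 1.29 log2 at percentile 100. Besides Ifi27, the ubiquitin-like modifier gene Isg15 was at least 10.6-fold higher, Bst2, which tethers enveloped viruses, at least 8.17-fold, and Usp18, which removes Isg15 from proteins, at least 5.77-fold. The median fell to 0.55 log2 without background correction and to 0.47 log2 without a filter on dim genes, and stayed at percentile 100.

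Muscle genes were also higher. Of 20 on the array 11 were detected, all 11 of them in the Dnmt1-null line and 6 in the control, and 8 were higher, 0 lower and 3 in between. Tnnt1, a slow-muscle troponin gene, was 10.8-fold higher, Acta1, the skeletal muscle actin gene, 8.79-fold, Tnnc2, a fast-muscle troponin gene, at least 4.46-fold, and Myl1, a myosin light chain gene, 4.11-fold. The list median was 1.91 log2 at percentile 100, and 0.92 log2 over all members without a filter on dim genes.

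Markers of other tissues were mostly not detected. Of 20 epithelial markers on the array 4 were detected, 3 in the Dnmt1-null line and 1 in the control. The keratin genes Krt14 (at least 8.74-fold) and Krt7 (at least 7.63-fold) were higher and 2 markers in between. The epithelial list median was 1.78 log2 at percentile 99.9, and 0.085 log2 at percentile 70.5 with a detection p-value under 0.05. Of 15 endothelial markers 3 were detected. Eng, a co-receptor of TGF-beta, was 9.37-fold higher, and Flt1 and Egfl7 differed by -0.78 and -0.51 log2, so the list median (-0.51 log2, percentile 4.65) and the list mean (0.64 log2) differed in sign, and over all members without a filter the median was 0.00081 log2. Of 15 haematopoietic markers 1 was detected, Cd14, a receptor subunit for bacterial lipopolysaccharide, which was 2.23-fold higher, and below 2-fold without background correction and with an offset of 50. Neural and glial markers had 7 of 19 detected, 2 lower and 5 in between, with a list median of -0.82 log2 at percentile 0.19. Map2, a microtubule-associated protein gene of neurons, was 3.03-fold lower and Gap43, a growth cone gene, at least 2.46-fold. The neural call was lost with the mean of all probes (-0.17 log2, percentile 17.9), with bounded differences (-0.26 log2, percentile 11.2) and over all members without a filter (0.019 log2). Map2 fell below 2-fold with the mean of all probes, and Gap43 without background correction and with an offset of 50. Of 19 trophoblast and extraembryonic markers 6 were detected and all 6 were in between, among them Dab2 (-0.62 log2) and Gata2 (0.16 log2), with a median of 0.10 log2 at percentile 79.4, which turned to -0.0051 log2 under median scaling and -0.0048 log2 with the authors' values.

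**Figure D3:**
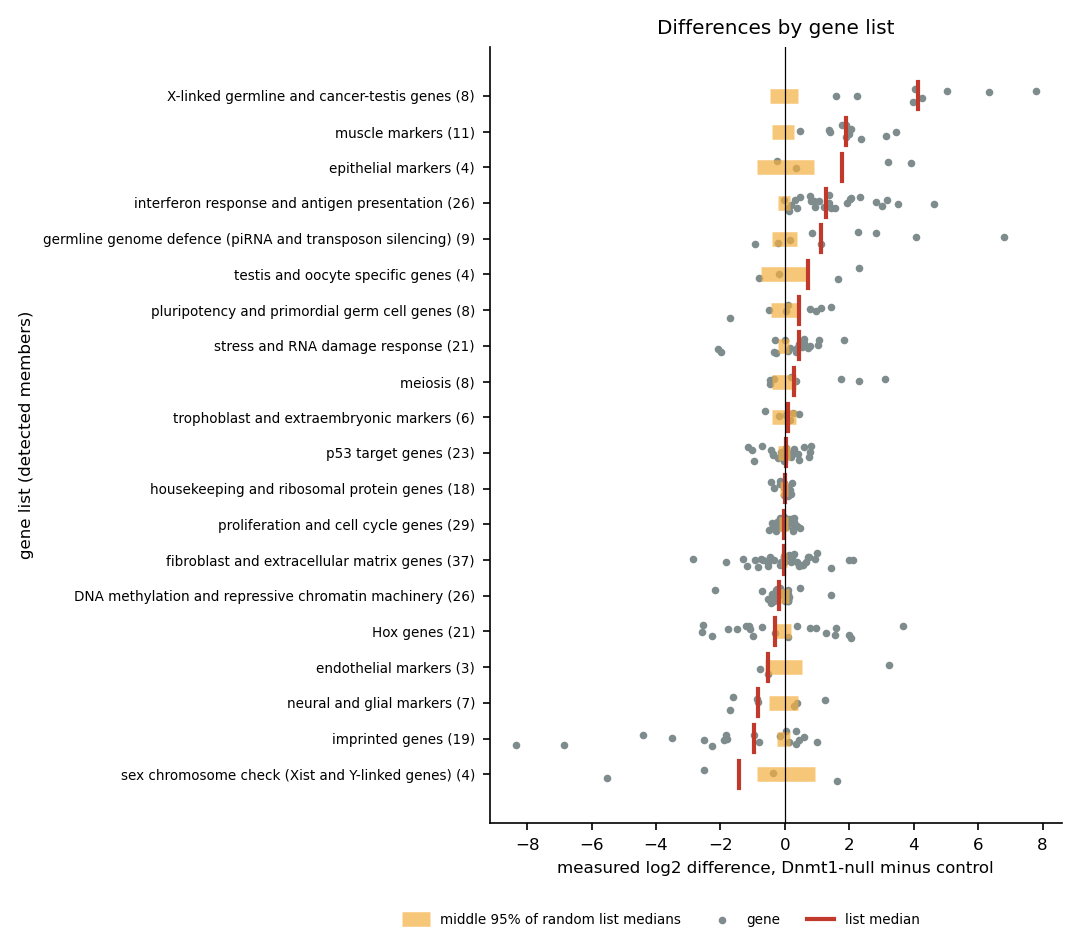
Measured log2 difference, Dnmt1-null minus control, of the detected members of each gene list (grey points). Red bars are list medians and orange bars the middle 95% of the medians of 10000 level-matched random lists. The medians of the X-linked germline (4.14), muscle (1.91) and interferon (1.29) lists lie above their orange bars and that of the imprinted list (-0.97) lies below.

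Genes of the fibroblast state and of growth had list medians near 0. Of 42 fibroblast and matrix genes 37 were detected, and 4 were higher, 4 lower and 29 in between, with a median of -0.02 log2 at percentile 54.4. The thrombospondin gene Thbs2 (4.33-fold) and S100a4 (3.98-fold) were higher, and Dcn and the homeobox gene Meox1 (at least 3.80-fold, and below 2-fold without background correction) lower. Thbs1 (2.68-fold) and Col5a2 (2.00-fold) were the other higher members, and Fbln1 (2.49-fold) and Prrx1 (2.26-fold) the other lower ones, all named after their values were seen. All 29 detected proliferation genes, of 31 on the array, lay within 2-fold, with a median of -0.013 log2 at percentile 60.2. Among them the replication gene Mcm4 differed by -0.27 log2 and the cyclin gene Ccnd1 by 0.25 log2. All 18 detected housekeeping genes, of 19, lay within 2-fold, with Tubb5 at -0.16 and Gapdh at 0.06 log2. Their median was 0.019 log2 at percentile 78.4 and their mean -0.0011 log2. The median of the matrix list changed sign under median scaling (0.033 log2), with the authors' values (0.038 log2), under cyclic loess (0.0042 log2) and on re-centring (0.013 log2). That of the proliferation list did so under cyclic loess (0.020 log2), on re-centring (0.019 log2) and with the mean of all probes (0.0048 log2).

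Of 30 p53 target genes 23 were detected, 2 were lower, 0 higher and 21 in between. Sesn1, a stress-induced inhibitor of growth signalling, was 2.23-fold lower and Fas, a death receptor gene, 2.03-fold. Both fell below 2-fold without background correction and with the mean of all probes, and Fas did so under 3 further settings. Their median of 0.02 log2 at percentile 73.7 and their mean of -0.03 log2 differed in sign, and the median turned to -0.094 log2 under median scaling and -0.096 log2 with the authors' values. In the list of DNA methylation and chromatin machinery 26 of 33 genes were detected, and Dnmt1 alone passed 2-fold. Uhrf1, which brings Dnmt1 to replicated DNA, differed by 0.13 log2 and the deacetylase gene Hdac2 by -0.44 log2, and the median was -0.19 log2 at percentile 3.44. It lay outside the limits of random lists under 5 of 11 alternatives, down to percentile 0.72 with a detection p-value under 0.05. Stress response genes had 21 of 23 detected, 3 higher, 2 lower and 16 in between, with a median of 0.43 log2 at percentile 100. Nqo1 (3.55-fold) and Hmox1 (2.07-fold), of the oxidative stress response, and the heat shock gene Hspb1 (2.05-fold, named after its value was seen) were higher, and Hmox1 fell below 2-fold under 5 settings. The immediate early genes Egr1 (4.26-fold) and Fos (3.95-fold) were lower.

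Hox genes, which mark position along the body axis, went both ways. Of 38 on the array 21 were detected, and 5 were higher, 8 lower and 8 in between, with a median of -0.31 log2 at percentile 1.51. Hoxd4 was at least 5.40-fold lower, Hoxa2 at least 5.21-fold and Hoxb2 4.80-fold, while Hoxc10 was at least 10.9-fold higher. Hoxc9 (4.15-fold), Hoxa7 (2.94-fold), Hoxd10 (at least 2.58-fold) and Hoxa11 (at least 2.37-fold), named after their values were seen, were the other higher members. The list call was lost with the authors' processed values, at percentile 5.36, and without a filter on dim genes, at percentile 45.6.

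**Figure D4:**
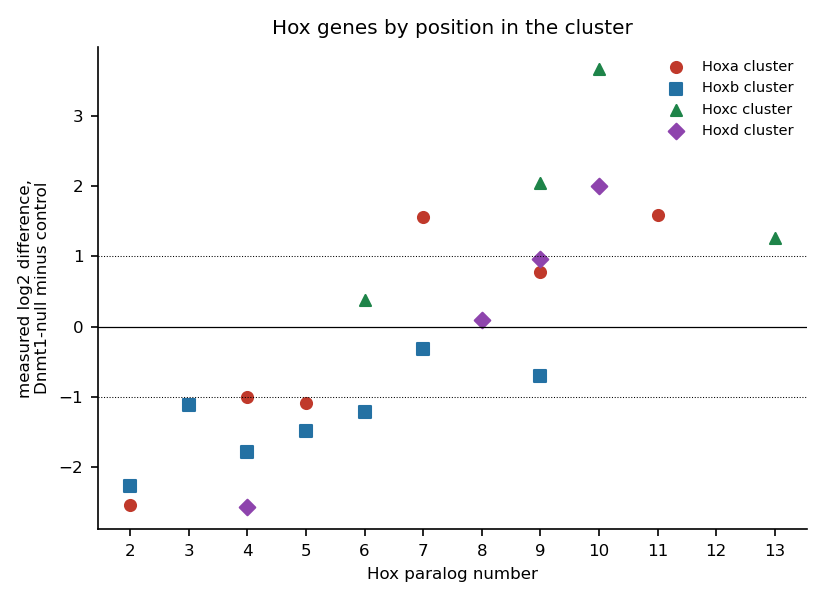
Measured log2 difference, Dnmt1-null minus control, of the 21 detected Hox genes (y axis) against their paralog number, which counts position within a cluster (x axis). Symbols mark the clusters, the solid line marks no difference and the dotted lines 2-fold. Genes beyond the lower dotted line have paralog numbers from 2 to 6 and genes beyond the upper one from 7 to 13.

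Sex chromosome genes differed between the lines. Of 8 on the array 4 were detected, 3 of them in the control and 1 in the Dnmt1-null line. Of these 4, 2 were lower, 0 higher and 2 in between, with a median of -1.44 log2 at percentile 0.11. The median was -0.93 log2 with bounded differences and -0.60 log2 without background correction, and the call was lost without a filter on dim genes, at -0.014 log2. Eif2s3y and Kdm5d, a Y-linked histone demethylase gene (at least 3.0-fold lower), were detected in the control alone, and Kdm5d fell below 2-fold without background correction and with normexp and an offset of 50. Xist, the RNA that silences an X chromosome, was named outside the rule. It was detected by 2 of 2 probes in the Dnmt1-null line and by 0 in the control. By its brighter probe it was at least 1.84-fold higher, and the other probe gave a smaller limit. Over 213 X-linked genes and 6633 autosomal genes detected on both arrays, the median difference of X-linked genes exceeded that of autosomal genes by 0.02 log2 (95% bootstrap interval -0.05 to 0.07). The genotype and these sex chromosome differences fell together, since each line had 1 array.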

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

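The tests of dim-probe noise, of germ cells, of a silenced X chromosome, of scaling, of imprint loss and of a general decline were chosen only after the result was seen. Those of both X chromosomes being active and of other differences between the lines were set earlier.

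Probes without a gene symbol take no part in the gene comparison, and 35 of the 619 detected ones were higher by 2-fold or more in the Dnmt1-null line. This was 5.65% of them, against 4.16% of the detected named probes, and 29 (4.68%, against 3.27%) were lower. The probes ILMN_2737090 (26.6-fold) and ILMN_1225712 (24.4-fold) were higher, and ILMN_2725927 (20.3-fold) and ILMN_1238433 (at least 17.9-fold) lower, all chosen after their values were seen. No explanation was tested.

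Germline genes were higher in the Dnmt1-null line, 16 of 29 detected members of the pooled lists. Noise of dim probes was argued against by a count over all 127 germline genes on the array, detected or not. Of these 16 were higher, against at most 9 in 10000 random lists matched on the control level. This was also the count among the 29 detected members, so only the number of genes considered changed. Paralogs of similar sequence were counted separately among the 16 genes. Germ cells in the culture were predicted to bring their abundant transcripts together. In the Dnmt1-null line 29.8% of the genome defence and meiosis genes on the array (17 of 57) were detected, below the limit of 50%. The germ cell genes Ddx4 (4.98 log2), Sycp3 (4.63 log2) and Mael (4.59 log2) were not. Most of these genes were thus not detected, but this cannot exclude germ cells. The listed genes need not all be active in 1 germ cell type, and a small share of germ cells could leave most of them undetected. A difference between the cell lines other than the Dnmt1 genotype cannot be told apart from it, because each genotype had 1 sample. Loss of promoter methylation in the Dnmt1-null line is a biological explanation that may account for part of this pattern and was not tested, since methylation was not analysed here.

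Y-linked Eif2s3y and Kdm5d were detected in the control alone. Loss of low signals by scaling or background choice was argued against for Eif2s3y, whose smallest measured decrease over the alternatives was -3.43 log2, but stays open for Kdm5d, where it was -1.07 log2, within the scatter (0.57 log2) of the 2-fold limit. A Dnmt1-null line with 2 active X chromosomes was argued against by the X-linked genes, whose median exceeded that of autosomal genes by 0.022 log2, below the limit of 0.5. An XX line with 1 silenced X chromosome predicted Xist in the Dnmt1-null line alone, and Xist was detected there alone. Its 2 probes lay at 6.32 and 6.44 log2, near the lowest detected level of 5.66 log2 on that array. By the brighter probe the difference was at least 0.88 log2, and the other probe gave a smaller limit. This test asked only whether Xist was detected and was chosen after that was seen, so it cannot decide and the explanation stays open. A first test, of whether Xist reached the median level of detected probes, pointed against this explanation. That test was replaced because levels of different probes cannot be compared. An XY line that lost its Y chromosome and gained Xist with the loss of methylation could give the same values and was not tested.

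Imprinted genes were lower in the Dnmt1-null line, 9 of 19 detected members. A general decline of genes high in the control fibroblasts was argued against, since among random lists matched on the control level the imprinted median of -0.97 log2 lay at percentile 0, and the middle 95% of these lists ran from -0.25 to 0.11 log2. Loss of methylation at imprint control regions could move genes either way, and 75% of the 8 moved genes with a predicted direction (6) followed it, between the limits of 50% against and 80% for the explanation, so this stays open. The share itself cannot decide, since 5 of the 8 were predicted lower and a decline of the list for any reason would meet those predictions. All 5 moved genes predicted to be lower were so (Igf2, Igf2r, Cdkn1c, Dlk1 and Grb10), but of 3 predicted to be higher 1 was (Ndn) and Mest and Nnat were lower. In all, 8 detected genes were predicted to be higher. Of the others, named after their values were seen, Impact (0.60 log2), Peg10 (0.42), Snrpn (0.34) and Mkrn3 (0.34) were higher within 2-fold. Inpp5f (-0.97 log2) was lower within 2-fold, and Cd81 (0.13 log2), predicted to be lower, did not move. Other differences between the lines stay open too.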

How the results depend on the processing

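Re-centring and leaving out X-linked and Y-linked genes were tests chosen only after the data were seen. Against 348 higher and 287 lower genes, the counts were 181 and 132 without background correction, 225 and 175 with normexp and an offset of 50, 711 and 718 at 1.5-fold, 171 and 121 at 3-fold, and 113 and 75 at 4-fold. All genes counted without background correction or with normexp and an offset of 50 were among those of the main setting, and these settings leave a larger additive signal in dim genes, which shrinks their folds. With the authors' processed values 449 genes were lower, 285 of them shared with the main setting, and the cause was not tested. The other settings gave 260 to 429 higher and 203 to 355 lower genes. The median difference of genes detected on both arrays was -0.107 log2 under median scaling and -0.108 log2 with the authors' values, against -0.03 log2 in the main setting, and it lay within 0.1 log2 of zero under the others. Dnmt1 stayed lower under all settings, by -1.88 to -2.32 log2. All 75 named genes past 2-fold kept their direction under every setting that held them, and 62 of them passed 2-fold without background correction, 67 with normexp and an offset of 50, 69 with neqc and an offset of 50, 70 with the mean of all probes, and 73 or more under the rest, except that 65 of 65 did so without X-linked and Y-linked genes. The interferon median was 0.55 log2 without background correction, 0.78 log2 with normexp and an offset of 50, 0.47 log2 without a filter on dim genes and 0.79 log2 with the mean of all probes (the cause was not tested), and the muscle median was 1.10 log2 without background correction and 0.92 log2 without a filter. Without a filter on dim genes the X-linked germline median was 0.12 log2, and the pluripotency, neural and endothelial medians changed sign, to -0.019, 0.019 and 0.00081 log2, because undetected members entered these lists. The X-linked germline, interferon, muscle and stress lists stood apart from random lists under all 11 alternatives, and the imprinted and germline genome defence lists under 10 of 11. Signal over background set the limits for dim genes, whose folds are lower limits where a line had no detected signal.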

Other observations

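All tests in this part were chosen only after the result was seen, and so were the genes named here outside the rule.

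Some genes outside the lists also passed 2-fold, and no grouping among them was tested. Higher in the Dnmt1-null line were Mlkl, the executor of necroptosis (6.24-fold), the myosin light chain gene Mylpf (6.18-fold), and Rapsn, which clusters acetylcholine receptors (at least 5.12-fold). The prolactin-family genes Prl2c3 (8.03-fold) and Prl2c4 (8.22-fold) were higher too, and their sequences are so alike that their probes cannot be taken as separate measurements. Lower were Igfbp5 (7.84-fold), Igfbp2 (6.80-fold), Gpc3, a cell-surface proteoglycan gene (at least 7.46-fold), and Ripk3, the kinase that activates Mlkl (2.05-fold).

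Genes that moved the same way lay next to each other, in the order of detected genes along the chromosomes, somewhat more often than random sets of these genes. There were 24 neighbouring pairs of higher genes, against a median of 15 and an upper end of the middle 95% of 23 in 10000 random sets, and 20 pairs of lower genes, against 10 and 17. The highest random counts were 31 for higher and 26 for lower genes, above the counts seen. Paralogs of similar sequence that lie side by side can count as a pair, and they were not set apart here. Hoxa2, Hoxa4 and Hoxa5 formed a run of 3 lower genes, Adcy4, Ripk3 and Nfatc4 another, and Ssxb8, Fthl17f and Xk a run of 3 higher genes on the X chromosome.

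Across the 21 detected Hox genes, pooled over 4 clusters, which are not independent replicates, the difference rose with the paralog number with a Spearman rho of 0.868, and 0.825 with lower limits in place of measured values. Within clusters, of 4 to 7 detected genes each, rho was 0.886 (Hoxa), 0.75 (Hoxb), 0.40 (Hoxc) and 1.0 (Hoxd), too few genes to compare the clusters. All detected Hoxb genes had differences below 0 (-2.26 to -0.31 log2) and all detected Hoxc genes above 0 (0.38 to 3.67 log2), while Hoxa and Hoxd genes went both ways. The cluster of a gene can therefore also enter the pooled rho. Of 10 detected genes with paralog numbers up to 6, 8 were lower and 0 higher (median -1.35 log2), and of 11 with numbers of 7 and above, 5 were higher and 0 lower (median 1.27 log2). A hypothesis is that the 2 cell lines keep Hox patterns of different body positions, which may reflect where in the embryo each culture came from. An effect of Dnmt1 loss on the clusters stays open, since each genotype had 1 line.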
